A study of Bos taurus with 8 samples.

How the data were processed

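Total RNA of the semitendinosus muscle of 12 bulls aged 15 months was measured on 8 bovine 2-colour Agilent arrays, extracted with Trizol per the labels. Each array carried 1 bull of a marbled breed (4 Hereford, 4 Holstein-Friesian) and 1 of 4 Limousin bulls. Hereford was labelled with Cy5 against Limousin in Cy3 on 1 slide, and Limousin with Cy5 against Holstein-Friesian in Cy3 on the other. The deposited labels give each Limousin bull the same number on both slides, so the replicate number marks the bull and pairs the arrays.

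Slides were scanned and extracted with Agilent Feature Extraction 10.7.3.1 per the file headers and the submitters' processing notes. Spot and local background brightness stood as intensity per the file headers, as the median over pixels in each channel. Processed signals, also given as intensity per the file headers, were background-subtracted with spatial detrending and dye-normalized within the array. The deposited value table held log10 ratios of Cy5 over Cy3, equal to the log ratio of the scanner output in 44407 of 44407 spots on every array. The series text describes the Holstein-Friesian arrays as turned to make Limousin the control, whereas the deposited table held them as Limousin over Holstein-Friesian. All value columns were mapped to samples (0 left). Other columns used were the flags for spots well above background, saturated, or outlying, per the file headers.

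The plan named mean signals, but the deposited scanner output held none, so median signals were used. Analysis ran in R 4.3.3 with limma 3.58.1, statmod 1.5.0, the data.table package (1.17.8) and jsonlite 2.0.0, and plots were drawn with matplotlib 3.10.9. Background was corrected with normexp and an offset of 50, and each array was normalized with loess (span 0.3, controls given no weight). Ratios were turned to breed over Limousin. Control spots and outlier spots were left out, leaving 42990 spots per array before outliers, and spots of 1 probe were averaged over 21475 probes. A probe was kept when at least 4 of its 16 channel readings were well above background, a reading counting when a share of at least 0.5 of the spots was; 17061 probes passed and 12961 were above background in all readings.

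Probe accessions were matched to symbols through a RefSeq table of assembly ARS-UCD2.0, used for names only because the array annotation follows build Btau_3.1 per the file headers. It named 8297 probes of 7788 genes. Of the kept probes, 7025 carried a symbol, for 6642 genes. Probes without one were counted but not named. A gene was represented by its brightest kept probe. In 365 genes with more than 1 kept probe, the signs of the probes differed in 119 for Hereford, 127 for Holstein-Friesian, 107 for the marbled breeds together and 143 for the difference, and 0 genes had probes called in opposite directions.

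Breed means were fitted over all 8 arrays with lmFit and eBayes of limma, and each breed was tested against Limousin, as was the difference between breeds. The marbled comparison used 4 values per probe, each the mean of the Hereford and Holstein-Friesian log2 ratios of 1 Limousin bull. A dye effect shared by the slides cancels in that mean and adds up in the difference. All tests were two-sided, with a call at a Benjamini-Hochberg adjusted p under 0.05 over 17061 probes. SD values describe the 4 arrays or bulls of a comparison. A Limousin dye check compared each Limousin bull in Cy5 with itself in Cy3 across slides.

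Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 25 lists held 508 genes, of which 504 matched a symbol and 319 had a kept probe. They cover adipocyte identity, fat synthesis, lipid uptake and droplets, fatty acid oxidation, oxidative phosphorylation, glycolysis, slow and fast fibres, collagen, myogenesis, proteolysis, insulin signalling, Wnt and BMP signalling, heat shock, immediate early genes, ribosomal proteins, interferon response, MHC, and markers of endothelium, fibroblasts, smooth muscle, macrophages, lymphocytes, blood and nerve. Lists of at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Results of fry are for a shared direction, unless its mixed test, which counts changes in either direction, is named. List p-values were adjusted over the 25 lists of a comparison.

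Genes were named by rule. For each breed and for the marbled breeds, these were the 8 largest rises and the 8 largest falls among named genes that passed with the same direction in every array or bull. Added to them were the 2 to 4 members with the smallest p of each list that passed, the 3 with the smallest p of each list on fat, and FABP4, ADIPOQ, PPARG, SCD, FASN, LEP, THRSP, LPL, MYH7 and MSTN where measured. ADIPOQ and FASN had no kept named probe. For the difference, the 4 largest in each direction were named. Some genes chosen by these rules are not reported here, but they stay in the counts. Other genes in the text are list members or were chosen after their values were seen.

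The pairing of arrays by bull was checked in the data. Deviations of the Hereford and Holstein-Friesian arrays of the same bull correlated across probes at 0.415, 0.273, 0.500 and 0.0987 for bulls 1 to 4, the last of them below its highest correlation with another bull's array (0.144). Within the Limousin channel, deviations in Cy3 and Cy5 of the same bull correlated at 0.402, 0.876, 0.757 and 0.620, and all between different bulls lay below 0. The consensus correlation within bulls was 0.305.

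The pipeline was tested on simulated data with 50 changed probes at each fold among 17061. In the Hereford simulation it recovered 66%, 88%, 96% and 100% at 1.5-, 2-, 4- and 8-fold, and in the Holstein-Friesian simulation 72%, 88%, 96% and 100%. For the marbled comparison the shares were 66%, 86%, 96% and 100%, and for the difference 22%, 84%, 96% and 100%. False calls numbered 13 of 188 calls, 20 of 198, 5 of 179 and 2 of 153 for these in turn, and with no simulated effect there were 0 calls in each. In the Hereford and Holstein-Friesian simulations the false share was thus above the 0.05 aimed at. A simulated moved list was called in the marbled comparison, with 0 other lists of 25. The simulated probes were drawn independently of each other, so this does not measure false list calls among correlated genes. Their noise was normal, with the variance already moderated by eBayes as the true spread of each probe and 1 bull correlation for all. Real spreads may differ more between probes, so the shares recovered may lie above those reached in the real data.

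Alternatives covered no background subtraction, the processed signals centred on their median, median centring in place of loess, Aquantile scaling between arrays, the deposited ratio table, no filter on dim probes, and a filter on all 16 readings. Others were a trended and robust prior, array weights, the 4 arrays of a comparison alone, a minimum 1.5-fold change, and the mean over a gene's probes. The Limousin bull was also fitted as a random block, or dropped as a block, and each replicate was left out in turn. A same-dye alternative compared each breed with its Limousin bull in the same dye on the other slide. Its forms for the difference, the lists of the difference and the overlap of breeds were chosen after the data were seen. Probe coordinates were not used here.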

Results

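Muscle of the well-marbled Hereford and Holstein-Friesian breeds was set against muscle of the lean Limousin breed, in 4 bulls of each breed aged 15 months. The tissue was the semitendinosus, a locomotor muscle of the hind limb. Each of 8 arrays carried a marbled bull and a Limousin bull in different dyes, and the same 4 Limousin bulls served on both slides. Median net signal over background was 97 to 139 intensity units in Hereford, always in Cy5, and 30.5 to 46.5 in Holstein-Friesian, always in Cy3. In Limousin it was 63 to 88 in Cy3 and 96.5 to 118 in Cy5. Breed cannot be told apart from dye and slide in these levels. Of 21475 probes, 16213 to 16979 were well above background in Hereford, 13939 to 14823 in Holstein-Friesian and 14931 to 17094 in Limousin. Each array held 6 to 29 outlier spots and 0 saturated spots, and observed and designed spike-in ratios had an r squared of 0.983 to 0.998. The number of arrays limits the precision of every value given here.

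The first comparison asked what the muscle of both marbled breeds shares against Limousin. Transcription factors of the immediate early class, which cells switch on quickly after a stimulus, rose in the marbled breeds, with ATF3, MYC, FOS, KLF4 and JUN among them. ATP2A2, the calcium pump of slow-twitch fibres, and MYH7, their myosin heavy chain, rose as well. MT2A, which encodes a metallothionein that binds zinc and copper, fell, and so did PVALB, the calcium buffer of fast-twitch fibres. In limma, ATF3 was higher by 3.52 log2 (SD 0.95, n = 4 bulls, adjusted p = 0.048), with a Hereford ratio of 2.77 and a Holstein-Friesian ratio of 4.26. MYC was higher by 2.03 (SD 0.29, limma adjusted p = 0.0256) and KLF4 by 1.65 (SD 0.08, limma adjusted p = 0.0095). FOS, higher by 1.86 (SD 0.17, limma adjusted p = 0.0095), drew on Holstein-Friesian, with log2 ratios of 0.25 in Hereford and 3.47 in Holstein-Friesian. JUN (1.56), ATP2A2 (1.31) and MYH7 (1.12) each had a limma adjusted p of 0.0458, and IFRD1 (1.73) and ZBTB21 (1.30) also rose. MT2A fell by 3.26 log2 (SD 0.33, limma adjusted p = 0.0095), with -3.45 in Hereford and -3.07 in Holstein-Friesian and a lower level on all 8 arrays. PVALB fell by 1.34 log2, followed by SLC29A2 (-1.01), ARMC2 (-0.94), CCDC12 (-0.94), ABCF2 (-0.93), PSMA5 (-0.88) and VPS72 (-0.83).

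Across 17061 probes, 102 differed between the marbled breeds and Limousin, 55 higher (29 named genes) and 47 lower (19 named genes). Gene calls in this comparison needed all 4 bulls. Without replicates 1, 2 or 4, limma called 0 probes (3340, 2339 and 2420 at an unadjusted p under 0.05), and without replicate 3 it called 1 (3155 unadjusted), so none of the 17 named genes that passed kept its call. Every named gene that passed, here or in the later comparisons, had the same direction in all 4 of its arrays or bulls. The naming rule required this of the largest rises and falls against Limousin. It also fixes their direction when a replicate is left out, so the shared direction is no further support. KLF4 without 1 replicate stayed between 1.62 and 1.68 log2 and MT2A between -3.36 and -3.11. With the Limousin bull as a random block over all 8 arrays, 910 probes passed, FOS (adjusted p = 0.0802 in limma) and MYH7 (0.0526) lost their call, and PDK4 (0.00901), CPT1B (0.00951), MYL3 (0.0111), UCP3 (0.0119), MX1 (0.0212), CIDEA (0.0274), PLIN2 (0.0373) and GYS1 (0.0409) gained one. With median centring 950 probes passed and 23.1% of them were higher, against 53.9% after loess.

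**Figure D1:**
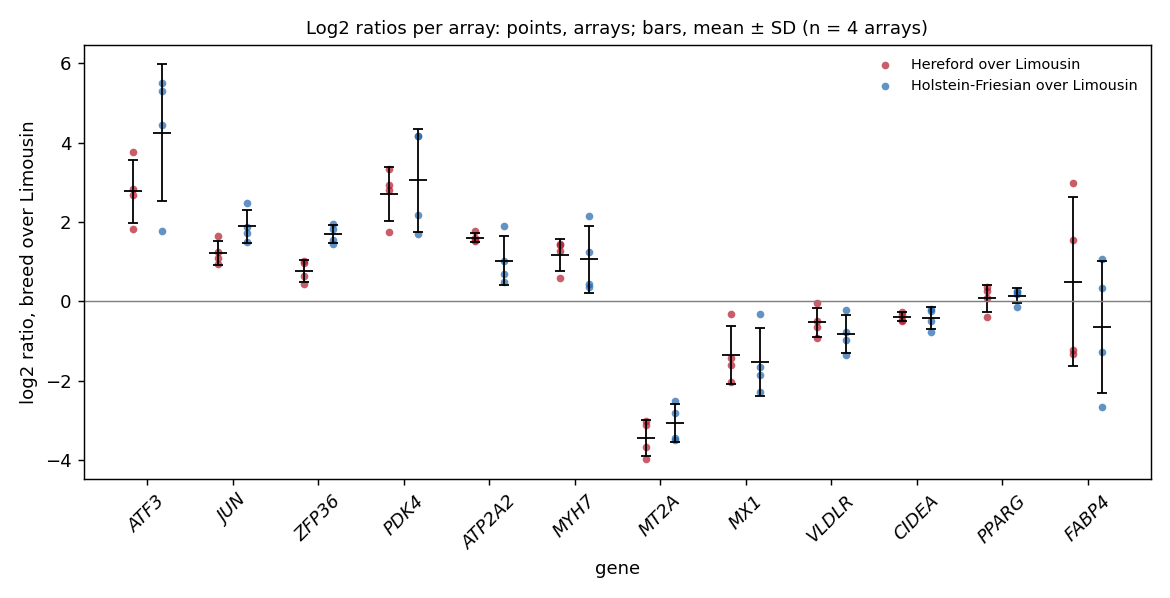
Log2 ratio of breed over Limousin for 12 genes on each array, with Hereford arrays in red and Holstein-Friesian arrays in blue, points for the 4 replicates and bars for mean and SD (n = 4). MT2A lay below 0 on all 8 arrays, with means of -3.45 and -3.07, and ATF3 above it, while FABP4 spread with an SD of 2.13 in Hereford and 1.67 in Holstein-Friesian.

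Gene lists placed these changes in muscle biology. Immediate early genes (16 measured) stood higher in the marbled breeds, with a median of 1.08 log2 and a camera adjusted p of 2.74e-10 (adjusted p = 0.138 with an estimated correlation). Of these, 6 rose, and 11 rose adjusted over the list alone; ZFP36, which marks short-lived messenger RNAs for decay, rose by 1.23 (limma adjusted p = 0.0427). Slow-twitch fibre genes, with MYH7 and ATP2A2 called among 10, had a median of 1.12 and a camera adjusted p of 0.000104 (adjusted p = 0.717 with an estimated correlation), and 6 rose adjusted over the list alone. MYL3, the slow light chain, stood at 1.36 (adjusted p = 0.0523 in limma). Genes of glycolysis and glycogen stood lower in the mean of both breeds, at a median of -0.21 (camera adjusted p = 0.000313; adjusted p = 0.717 with an estimated correlation). The breeds did not share this fall: the median was -0.62 in Holstein-Friesian, with all 16 genes lower, and 0.17 in Hereford, with 11 of 16 higher, or -0.12 in Hereford read in the same dye. With median centring it was 0.66 in Hereford and -1.32 in Holstein-Friesian. None of the 16 glycolysis genes passed over all probes and 3 fell adjusted over the list alone, with GPI at -0.46 (0.0573), GYS1 at -0.58 (0.0633) and PGK1 at -0.61 (0.0906), all adjusted in limma.

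Ribosomal protein genes stood slightly higher in the marbled breeds and interferon response genes lower. The ribosomal list (22 measured) had a median of 0.19 and a camera adjusted p of 0.000104 (adjusted p = 0.717 with an estimated correlation), with RPS6 at 0.31, RPL23 at 0.27 and RPL3 at 0.23 log2. Interferon genes, of which 9 were measured, had a median of -0.26 and a camera adjusted p of 0.00536 (adjusted p = 0.717 with an estimated correlation), and of -0.69 with processed signals and -0.70 with the deposited ratios. The antiviral MX1 stood at -1.44 (limma adjusted p = 0.0927), and ISG15 at -1.67 (0.209), and 1 gene fell adjusted over the list alone; IFIT3 was not well above background in the marbled breeds. Both of these lists lost their call with median centring (0.07, camera adjusted p = 0.202, and -0.17, camera adjusted p = 0.215). All 5 lists kept their call and direction without each replicate in turn, and in fry only the immediate early list passed (fry adjusted p = 0.0045). Changing the signs of single bulls, in 8 arrangements with the real one, gave up to 10 called lists against 5.

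Marbling is fat stored within the muscle, so the lists on fat bear on the question most directly. None of them passed for a shared direction. The mixed test of fry passed for adipocyte identity (fry adjusted p = 0.0006), fat synthesis (0.0082), lipid uptake (0.0061) and oxidation (0.0049). It also passed for lists not on fat, such as oxidative phosphorylation (fry adjusted p = 0.0006). Genes of adipocyte identity (15 measured) had a median of -0.04 log2 (camera adjusted p = 0.475), with 2 lower adjusted over the list alone. FABP4, the fatty acid carrier of fat cells, stood at -0.08 with an SD of 1.82 (n = 4 bulls, limma adjusted p = 0.976). PPARG, the master regulator of adipogenesis, stood at 0.11, LPL at 0.11, AGPAT2 at -0.20, THRSP at -0.05, CIDEA at -0.41 and G0S2 at -0.55 (limma adjusted p = 0.0646), while LEP was well above background in only 3 of 8 readings of the marbled breeds. Fat synthesis (13 measured) had a median of 0.0027, a mean of -0.0031 and a downward test (camera adjusted p = 0.902), with 1 gene higher adjusted over the list alone; its median was -0.09 with median centring. Among its members SCD stood at -0.15, ACLY at -0.29, ME1 at -0.22 and GPAM at 0.55 (limma adjusted p = 0.0521). Genes for lipid uptake and droplets (13 measured) had a median of -0.11 (camera adjusted p = 0.804), with VLDLR at -0.68 (limma adjusted p = 0.0564), PLIN2 at -0.58 and PLIN3 at 0.42, and with 1 higher and 2 lower adjusted over the list alone. Fatty acid oxidation (16 measured) had a median of -0.03, a mean of 0.14 and a downward test (camera adjusted p = 0.902), with 3 higher and 3 lower adjusted over the list alone. Its members went apart: PDK4, which spares pyruvate while fat is burnt, stood at 2.88 (SD 0.87, limma adjusted p = 0.0521), whereas UCP3 stood at -1.27 (0.0523) and CPT1B at -0.46 (0.0556). MSTN, the growth inhibitor myostatin, stood at -0.35 (limma adjusted p = 0.272).

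The other lists did not pass for a shared direction between the marbled breeds and Limousin. The mixed test of fry passed for some, such as heat shock (fry adjusted p = 0.0015), proteolysis (0.0042) and fast-twitch fibres (0.0067). It did not pass for others, such as endothelium (0.669) and macrophages (0.756). Fibre and growth lists had medians of -0.08 log2 for fast-twitch fibres (camera adjusted p = 0.776; PVALB fell), -0.07 for myogenesis (0.902), -0.14 for proteolysis (0.259), 0.03 for insulin signalling (0.776), -0.03 for Wnt and BMP signalling (0.902) and -0.01 for oxidative phosphorylation (0.902). Myogenesis had a mean of 0.02 with a downward test, and Wnt and BMP signalling a mean of 0.05 with an upward test. Proteolysis had 3 genes higher and 4 lower adjusted over the list alone. Connective tissue and vessel lists had medians of -0.07 for collagen (camera adjusted p = 0.804), -0.10 for fibroblasts (0.804), 0.17 for smooth muscle (0.0952), 0.03 for endothelium (0.776), 0.10 for nerve (0.259) and 0.11 for blood (0.776). Immune and stress lists had medians of 0.0059 for macrophages (camera adjusted p = 0.902), 0.06 for lymphocytes (0.461), 0.24 for MHC (0.416) and -0.03 for heat shock (0.717), where MT2A fell. With median centring the medians of smooth muscle (-0.02), endothelium (-0.01), macrophages (-0.04) and myogenesis (0.01) had the opposite sign, as did oxidative phosphorylation (0.0057) with processed signals.

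**Figure D2:**
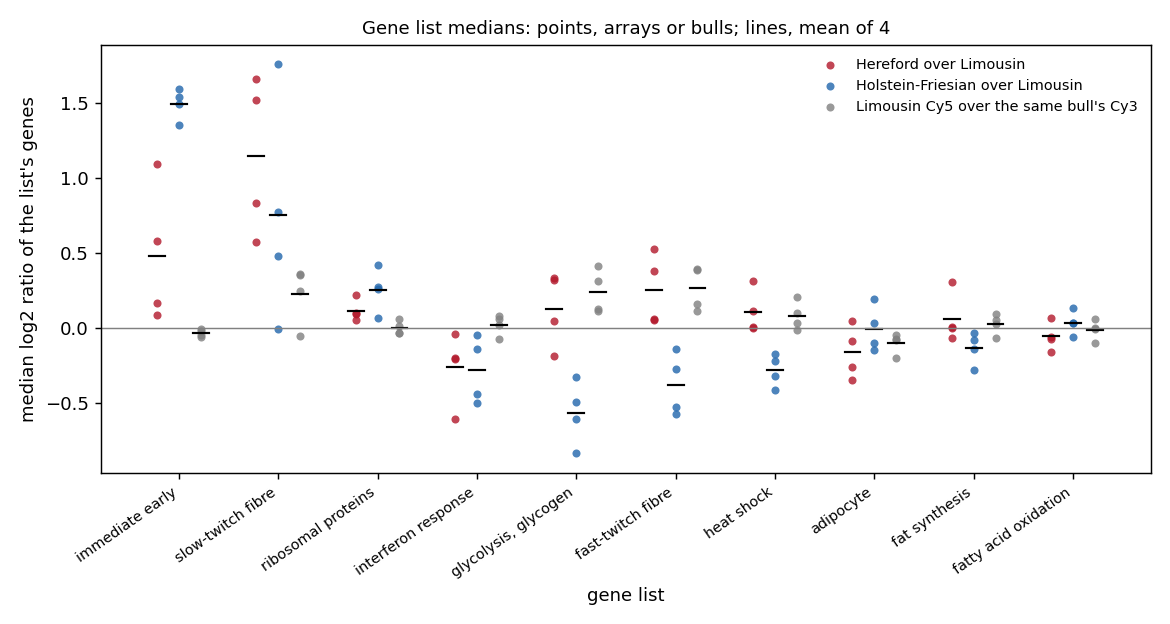
Median log2 ratio of breed over Limousin of 10 gene lists on each array (Hereford red, Holstein-Friesian blue, 4 replicates each, lines at the mean), with the Limousin dye check of each bull in grey. Immediate early genes had medians from 0.09 to 1.09 in Hereford and from 1.35 to 1.59 in Holstein-Friesian, and the ribosomal list, above 0 in Holstein-Friesian here, had a median of -0.45 with median centring.

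Hereford muscle was next set against Limousin. ATP2A2 and the slow light chains MYL3 and MYL2 rose, as did MYH7 and PDK4. So did ATF3 and JUN, the ketone body carrier SLC16A6, the growth arrest gene GADD45A, and INHA, a subunit of the hormone inhibin. MT2A fell, and so did the interferon-induced RTP4, the complement gene C4A, FDFT1 of sterol synthesis, CPT1B, which admits fatty acids to mitochondria, and the lipid droplet coat PLIN2. ATF3 was higher by 2.77 log2 (SD 0.79, n = 4, limma adjusted p = 0.0307), PDK4 by 2.71 (SD 0.68, 0.0168), MYL3 by 1.98 (SD 0.70, 0.00816) and ATP2A2 by 1.61 (SD 0.11, 0.00816). SLC16A6 (2.76), ETS2 (1.98), INHA (1.90), SYT4 (1.88), GADD45A (1.65), MYL2 (1.37), JUN (1.22), MYH7 (1.18) and ZFP36 (0.76) also rose. MT2A fell by 3.45 log2 (SD 0.46, n = 4, limma adjusted p = 0.00153), CPT1B by 0.81 (SD 0.07, 0.00382) and PLIN2 by 0.77 (SD 0.37, 0.0287). The further falls were PLAC8B (-1.79), RTP4 (-1.39), DDIT4L (-1.38), TMEM106A (-1.31), FDFT1 (-1.23), C4A (-1.23) and DUSP10 (-1.22). PPARD passed at -0.36 (limma adjusted p = 0.0272), yet stood at 0.14 (adjusted p = 0.518) when both breeds were read in the same dye.

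In Hereford, limma called 1218 probes, 579 higher (233 named genes) and 639 lower (270 named genes). The spread in that fit was pooled over the arrays of both breeds. From the Hereford arrays alone limma called 27 (3310 at an unadjusted p under 0.05), so the 1218 rested on the pooled fit. Holstein-Friesian arrays alone gave 839. Pairs of Hereford arrays correlated across probes at 0.0611 to 0.531, and pairs of Holstein-Friesian arrays at 0.403 to 0.595. The Hereford count also rested on replicates 2 and 4, with 45 probes without replicate 2, 30 without replicate 4 and 352 without replicate 3. Of the 24 named genes that passed, MT2A and CPT1B kept their call without every replicate in turn (CPT1B stood at -0.49 in the same dye and was itself called in the Limousin dye check, at -0.32 with a limma adjusted p of 0.0384, and lost its call with median centring, 0.0866), while 4 kept it without replicate 4 (these with MYL3 and INHA), 12 without replicate 3 and 18 without replicate 1. The bull as a block ended the calls of MYL2 (limma adjusted p = 0.0569) and MYH7 (0.0714) and gave 1 to MX1 (-1.35, 0.0414). In the same dye 13 of the 24 kept their call, and MYL2 (0.0587) and PLIN2 (0.0552) were among those that did not. Calls leaned higher with processed signals (69.1% of 881) and with median centring (87% of 315), against 47.5% here.

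Slow-twitch genes led the Hereford lists, with a median of 1.16 log2 and a camera adjusted p of 0.000316 (adjusted p = 0.601 with an estimated correlation); 4 rose, and 6 rose adjusted over the list alone. Read in the same dye, the slow-twitch median was 0.73, against 1.04 in Holstein-Friesian, and the difference between the breeds in this list did not pass (0.48, camera adjusted p = 0.138). Interferon genes stood lower (-0.26, camera adjusted p = 0.0152, and adjusted p = 0.601 with an estimated correlation), with 5 lower adjusted over the list alone. Their median was -0.90 with processed signals, -0.98 with the deposited ratios, and -0.92 (camera adjusted p = 0.0716) with readings all above background. MX1 stood at -1.35 (limma adjusted p = 0.0547) and IRF9 at -0.92 (0.0618), and IFIT3, not well above background in Hereford, was at least 1.26-fold higher in Limousin (0.0662). Immediate early genes had a median of 0.49 (camera adjusted p = 0.0167, and adjusted p = 0.601 with an estimated correlation); 6 rose, and 7 rose and 1 fell adjusted over the list alone. Ribosomal genes had a median of 0.14 (camera adjusted p = 0.0347, and adjusted p = 0.601 with an estimated correlation), with RPL6 at 0.38, RPL7 at 0.22 and RPS18 at 0.20, and lost the call with the bull as a block (0.0698). Without replicate 1 the interferon (camera adjusted p = 0.0898), immediate early (0.072) and ribosomal (0.0775) lists no longer passed, and without replicate 3 the immediate early median was 0.14 (0.121) and the ribosomal one 0.09 (0.117). In fry none of the 4 lists passed (6 lists at an unadjusted p under 0.05). The ribosomal call was also absent with processed signals (0.488), with the deposited ratios (0.609) and with readings all above background (0.0641).

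Fat genes showed no shared shift in Hereford. Adipocyte genes had a median of -0.12 log2 (camera adjusted p = 0.306), fat synthesis 0.17 (0.503), lipid uptake and droplets -0.0088 with a mean of 0.03 (0.909), and fatty acid oxidation -0.04 with a mean of 0.12 and a downward test (0.881). Lipid uptake and oxidation had medians of 0.35 and 0.19 with median centring, so neither of these directions was fixed. Adipocyte genes had 0.0035 there, or -0.10 relative to all probes, and -0.0011 in the same dye. FABP4 stood at 0.49 with an SD of 2.13 (n = 4, limma adjusted p = 0.789). SCD stood at 0.29, GPAM at 0.57, ME1 at 0.27, ACLY at -0.31, CIDEA at -0.39, G0S2 at -0.67, VLDLR at -0.53, LIPE at -0.25, ZNF423 at -0.24, LPL at 0.22, PPARG at 0.08, THRSP at 0.05, LEP at 0.02 and MSTN at -0.01, all with limma adjusted p-values above the threshold.

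Holstein-Friesian muscle was set against Limousin in the same way. ATF3, FOS, MYC, KLF4, JUN and ZFP36 rose, with GADD45G, the matricellular CCN1, and CFD, a complement protease that fat cells secrete. PDK4 and ATP2A2 rose here as in Hereford. MT2A and PVALB fell, and so did UCP3 of mitochondria, the collagen gene COL3A1, the oxygen store MB, the glycolytic PGK1 and TPI1, TNNC2 of fast fibres and ME1, which supplies reducing power for fat synthesis. ATF3 was higher by 4.26 log2 (SD 1.72, n = 4, limma adjusted p = 0.00948), FOS by 3.47 (SD 1.16, 0.0123), PDK4 by 3.05 (SD 1.29, 0.0112), MYC by 2.78 (SD 0.61, 0.00403) and KLF4 by 2.31 (SD 0.50, 0.00288). GADD45G (2.86), CCN1 (2.50), JUN (1.89), ZFP36 (1.69), CFD (1.17), ATP2A2 (1.02), PLIN3 (0.54) and RPL3 (0.35) also rose. DECR1 of fatty acid oxidation passed at 0.54 (limma adjusted p = 0.0136), and with median centring stood at -0.0069, or 0.19 relative to all probes, whereas RPL3 stood at -0.29, or -0.09 relative to all probes. MT2A fell by 3.07 log2 (SD 0.48, n = 4, limma adjusted p = 0.00142), UCP3 by 1.67 (SD 0.21, 0.0085) and ME1 by 0.71 (SD 0.11, 0.0058). The further falls were COL3A1 (-2.53), METTL21E (-2.02), PVALB (-1.90), SMTNL2 (-1.56), MX1 (-1.53), NDRG2 (-1.52), PGK1 (-1.27), MB (-1.02), VLDLR (-0.83), TNNC2 (-0.68), TPI1 (-0.65), HSPA8 (-0.57), GYG1 (-0.49), CIDEA (-0.42) and HSPE1 (-0.31).

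In Holstein-Friesian, limma called 1100 probes, 512 higher (269 named genes) and 588 lower (235 named genes). Without replicate 2 there were 78, without replicate 3 275 and without replicate 4 127. Of the 33 named genes that passed, 6 kept their call without replicate 2, namely GADD45G, KLF4, MT2A, UCP3, ZFP36 and JUN, and 9 without replicate 4, 16 without replicate 3 and 21 without replicate 1. In the same dye 8 kept it, among them FOS, MYC, KLF4, MT2A and UCP3. Read that way TPI1 stood at -0.08 (adjusted p = 0.663 in limma), TNNC2 at -0.11 (0.545) and ATF3 at 4.74 (0.0626), while MYH7 gained a call (0.0466). The bull as a block ended the calls of RPL3 (limma adjusted p = 0.0549) and VLDLR (0.0555). Processed signals moved the median of all probes to -0.12 and median centring to -0.20, and lower calls then prevailed, with 28.6% higher among 2411 and 29% among 6678, against 46.5% here.

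Immediate early genes had the highest median of the Holstein-Friesian lists (1.66 log2, camera adjusted p = 1.43e-11, and adjusted p = 0.123 with an estimated correlation); 11 rose, and 12 rose adjusted over the list alone. Glycolysis and glycogen genes stood lower (-0.62, camera adjusted p = 6.65e-08, and adjusted p = 0.357 with an estimated correlation), where 8 fell, and 11 fell adjusted over the list alone. In the same dye that median was -0.34. Fast-twitch genes, with TNNC2 and PVALB called, had a median of -0.38 (camera adjusted p = 0.0207, and adjusted p = 0.357 with an estimated correlation), with 3 lower adjusted over the list alone, but of -0.04 (0.913) in the same dye. Heat shock genes had a median of -0.19 (camera adjusted p = 0.0207, and adjusted p = 0.268 with an estimated correlation), with 3 lower, or 1 higher and 4 lower adjusted over the list alone, and did not pass in the same dye (0.0972). Without replicate 1 the fast-twitch list did not pass (camera adjusted p = 0.0778), nor the heat shock list without replicate 2 (0.0521), nor either with processed signals (0.0908 and 0.0628) or the deposited ratios (0.0836 and 0.0722).

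Ribosomal genes in Holstein-Friesian had a median of 0.25 (camera adjusted p = 0.000162, and adjusted p = 0.357 with an estimated correlation) and 8 rose adjusted over the list alone, but median centring reversed the median to -0.45, or -0.25 relative to all probes. RPS6 stood at 0.40 after loess. Slow-twitch genes had a median of 0.87 (camera adjusted p = 0.0456, and adjusted p = 0.749 with an estimated correlation), with ATP2A2 higher, MB lower and MYH7 at 1.06 (limma adjusted p = 0.0681); 3 rose and 1 fell adjusted over the list alone. The slow-twitch call was lost with the bull as a block (camera adjusted p = 0.159), without replicate 1 (0.249), with no background subtraction (0.0501), with no filter (0.0521), in fry (0.316) and with median centring (0.29), where the median was 0.37 relative to all probes. Macrophage genes had a median of 0.26 (camera adjusted p = 0.0456, and adjusted p = 0.749 with an estimated correlation), with CD14 at 0.49, C1QA at 0.83 and AIF1 at 0.62 and 1 higher adjusted over the list alone. That call was lost with the bull as a block (camera adjusted p = 0.128), in the same dye (0.235), without replicate 3 (0.245) or 4 (0.276), with no background subtraction (0.0501), with median centring (0.0607), with the mean over probes (0.0626) and in fry (0.316).

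Fat genes did not move together in Holstein-Friesian either. Medians were -0.0013 log2 for adipocyte genes (camera adjusted p = 0.825), -0.16 for fat synthesis (0.306), -0.08 for lipid uptake and droplets (0.60) and 0.05 for fatty acid oxidation (0.795), and with median centring -0.27, -0.21, -0.36 and -0.15 in this order relative to all probes. Adipocyte genes had -0.12 in the same dye. FABP4 stood at -0.64 with an SD of 1.67 (n = 4, limma adjusted p = 0.699), SCD at -0.59 (0.177) and MSTN at -0.68 (0.0702). GPAM stood at 0.54, ACLY at -0.28, LIPE at -0.30, THRSP at -0.14, PPARG at 0.14 and LPL at -0.0013, and ATP2A1, the calcium pump of fast fibres, at -0.82 (limma adjusted p = 0.0558). LEP was not well above background in Holstein-Friesian.

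Some genes were called in both breeds. MT2A fell in both, and ATF3, JUN, ZFP36, PDK4 and ATP2A2 rose in both. In limma, 82 probes were called higher and 117 lower in both breeds, against 17.4 and 22.0 for independent lists, and 48 in opposite directions against 39.1. Of the 199 that went the same way, 71 were also called in the marbled comparison. The Limousin bulls are shared, which ties the ratios together. In 100 simulated draws with these shared bulls and no breed effect, the highest count of probes called in both was 0. At an unadjusted p under 0.05, 1026 probes went the same way in both breeds, against a mean of 139 in the draws. How many calls would coincide where each breed has effects of its own was not tested. Log2 ratios of the breeds correlated at 0.286 across probes, which are not independent replicates. The draws were built with the correlation within bulls of 0.305, so the 0.305 they returned was set in advance. The covariance was 0.0281, against at most 0.00752 in the draws. With different Limousin bulls behind each breed, in 6 splits of the bulls, the covariance was 0.00352 to 0.0335. The count was 123 without replicate 1, 5 without replicate 2, 42 without replicate 3 and 8 without replicate 4, and 16 in the same dye.

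**Figure D3:**
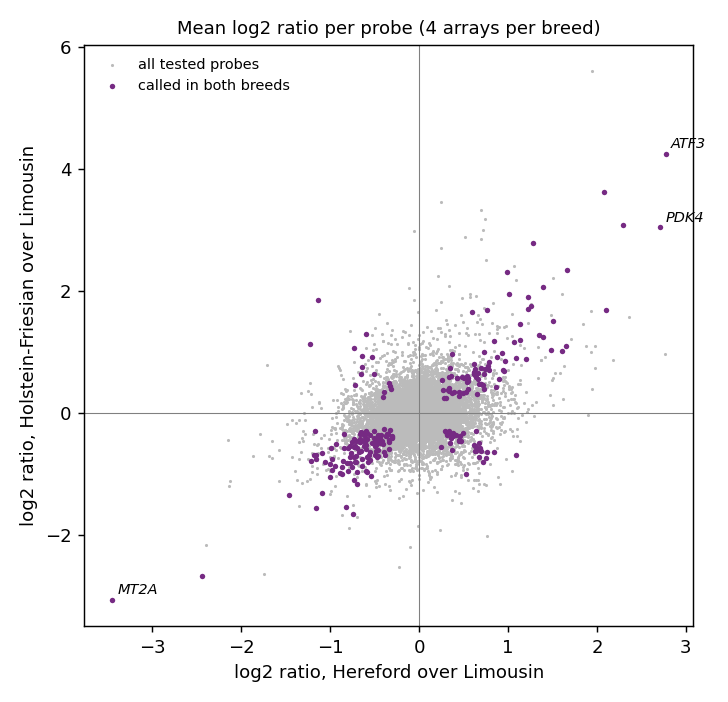
Log2 ratio over Limousin of each probe in Hereford (horizontal) and Holstein-Friesian (vertical), with the probes called in both breeds in purple. ATF3 and PDK4 stand at the upper right and MT2A, at -3.45 and -3.07, at the lower left, and the correlation across probes was 0.286.

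The difference between the marbled breeds was tested directly, gene by gene and list by list. INHA, the protease inhibitor LXN, the receptor EPHB3 and the oxygen store MB were higher in Hereford relative to Holstein-Friesian. The complement genes C4A and CFB, the GTPase RRAD and the stress gene GADD45B were lower in Hereford. INHA differed by 1.94 log2 (SD 0.77, n = 4, limma adjusted p = 0.0292), LXN by 1.80 (SD 0.27, 0.00242), EPHB3 by 1.53 (SD 0.31, 0.00299) and MB by 1.43 (SD 0.25, 0.0341). C4A differed by -2.36 (SD 0.46, n = 4, limma adjusted p = 0.0236), RRAD by -2.16 (SD 0.73, 0.033), GADD45B by -2.08 (SD 0.36, 0.0105) and CFB by -1.84 (SD 0.74, 0.0434). These SDs describe the 4 differences within bulls, whereas the p-values come from the fit over all 8 arrays, which leaves the pairing out. In that fit limma called 463 probes, 266 higher in Hereford (105 named genes) and 197 lower (113 named genes). Paired by bull it called 701, of which 325 were among the 463. The 8 genes kept their call when paired, with limma adjusted p-values from 0.0218 (LXN) to 0.0427 (CFB). Without replicates 2 or 4 it called 0 (2366 and 2217 at an unadjusted p under 0.05) and without replicate 3 24, and none of the 8 genes kept its call without replicates 2 or 4. In the same dye 282 probes were called. The median of all probes moved to 0.19 with processed signals and to 0.36 with median centring, with 82.5% of 1342 and 78.1% of 6219 calls higher in Hereford, against 57.5% here and 67.6% of 979 with the deposited ratios.

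Immediate early genes were lower in Hereford than in Holstein-Friesian, each against Limousin, and glycolysis genes higher. The immediate early median differed by -0.997 log2 (camera adjusted p = 2.34e-05, and adjusted p = 0.240 with an estimated correlation), with 8 lower adjusted over the list alone, and the macrophage median by -0.63 (0.00289, and adjusted p = 0.644 with an estimated correlation), with 3 lower. The glycolysis median differed by 0.64 (camera adjusted p = 7.38e-07, and adjusted p = 0.475 with an estimated correlation), with 8 higher adjusted over the list alone, and by 0.27 (0.0581) in the same dye. The heat shock median differed by 0.25 (camera adjusted p = 0.0133, and adjusted p = 0.240 with an estimated correlation), with 4 higher adjusted over the list alone, and by 0.20 (0.0815) in the same dye. The fast-twitch median differed by 0.51 (camera adjusted p = 0.00128, and adjusted p = 0.240 with an estimated correlation), with 5 higher adjusted over the list alone, but the sign turned in the same dye (-0.06, 0.936). Relative to all probes, median centring gave 1.55 for glycolysis, 1.5 for fast-twitch, 0.98 for heat shock, -0.58 for immediate early and -0.77 for macrophage genes. All 5 lists passed without each replicate in turn. Fast-twitch and heat shock genes did not pass with processed signals (camera adjusted p = 0.109 and 0.0687) or with the deposited ratios (0.0896 and 0.0638). In fry, glycolysis (0.0528) and macrophage genes (adjusted p = 0.194) did not pass.

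Reading the same Limousin bulls in both dyes showed how far dye and slide could move a gene. Slow-twitch, fast-twitch and glycolysis genes had medians of 0.28, 0.25 and 0.25 log2 in Cy5 over Cy3, and immediate early genes 0.0039. Single immediate early genes did move with dye and slide, with 4 of 16 called in this check and an SD over the members of 0.30. The outermost 1% of probes lay below -0.39 on the low side and above 0.44 on the high side. Across probes the check correlated at 0.691 to 0.762 between bulls 2 to 4, but at -0.138 to 0.202 between these and bull 1. Bull 1 enters these means and the same-dye ratios, so both may misstate the dye effect seen in bulls 2 to 4. The slow-twitch median was -0.05 in bull 1 and 0.25 to 0.36 in the others, and the fast-twitch median 0.39 against 0.11 to 0.39. In limma 803 probes were called, 296 higher and 507 lower, but without replicate 1 there were 5663 and without any other replicate limma called 0 (2291 without replicate 2, 2484 without 3 and 3094 without 4 at an unadjusted p under 0.05). Same-dye ratios had the sign of the calls in 98.7% of Hereford and 99.4% of Holstein-Friesian probes, with 268 and 164 of them called again.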

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

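The tests of immediate early genes and of slow-twitch and glycolysis genes were chosen after those results were seen, whereas the tests of other splits of the samples and of dye and slide in the difference between breeds were written before.

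Immediate early genes stood 1.08 log2 higher in the marbled breeds, and more so in Holstein-Friesian than in Hereford, although neither list test passed with an estimated correlation (camera adjusted p = 0.138 and 0.240). Dye and slide as the whole cause are argued against by the Limousin bulls. In them these genes had a median of 0.00394 log2 between Cy5 and Cy3, though 4 of the 16 were called. The loess curve as the whole cause is argued against by medians with median centring of 0.717 in Hereford and 1.07 in Holstein-Friesian. The 0.898 in the marbled mean adds little, because a dye curve shared by the slides cancels there. Stress or delay at slaughter could raise such genes too and stays open: the heat shock list had a marbled median of -0.0293, but its members went both ways, with MT2A falling by 3.26 log2, and so did the breeds, with 0.15 in Hereford (4 genes rose, 2 fell) and -0.19 in Holstein-Friesian (3 fell). Time from slaughter to freezing is not given in the sources used here. Breed is the explanation the design offers, and it was not tested apart from handling of the animals.

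Slow-twitch genes stood higher in the marbled breeds (1.12 log2) and glycolysis genes lower (-0.21), the latter with -0.62 in Holstein-Friesian and 0.17 in Hereford, where the same dye gave -0.12; neither marbled list passed with an estimated correlation (camera adjusted p = 0.717 for both). Dye as the whole cause is argued against by same-dye medians of 0.725 for slow-twitch genes in Hereford and -0.345 for glycolysis genes in Holstein-Friesian, though the latter is smaller than -0.62, so that dye may have added to it. With median centring the slow-twitch median was 1.01, but a dye curve shared by the slides cancels in the marbled mean, so this cannot decide on loess. By breed, median centring gave 1.72 in Hereford, against 1.16 after loess. In Holstein-Friesian it gave 0.17 against 0.87, where all probes had a median of -0.199, so the size of that rise depended on loess. For glycolysis genes median centring gave 0.66 in Hereford, where all probes had 0.0991, and -1.32 in Holstein-Friesian, so their sizes depended on loess too. With processed signals they had 0.07 in Hereford and -0.61 in Holstein-Friesian. The place of sampling within the muscle cannot be told apart from breed, since it is not given in the sources used here. The lowest of the 4 bull medians of slow-twitch genes was 0.385 in the mean of both breeds. In Holstein-Friesian alone the lowest was -0.0049, in replicate 4. A larger share of slow fibres in the marbled breeds is the biological candidate explanation and stays open with the place of sampling, untested. Fast-twitch genes had a median of 0.28 in Hereford (-0.09 in the same dye) and -0.38 in Holstein-Friesian (-0.04 in the same dye).

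Between the breeds 463 probes differed. Dye bias as the whole cause is argued against by the same dye, in which 94.2% of these probes kept their sign, and a median share of 0.655 of the change was left there, so that dye may account for part of it. The slide cannot be told apart from breed, because each breed had a slide of its own. Of 35 splits of the 8 arrays, 1 gave as many calls, the real one (463, highest other 2, from a split that kept a pair of arrays together). Most of these splits ignore the shared Limousin bulls, so they cannot decide whether chance is excluded. The 8 that part all pairs of arrays are too few for a share under 0.05 (463, highest other 0).

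Other results had too few arrangements for a share under 0.05, with 8 sign changes of the 4 bulls each. In these, 1 of 8 gave as many calls for Hereford (1218, highest other 0), Holstein-Friesian (1100, highest other 0), the marbled breeds (102, highest other 0), both breeds together (199, highest other 0) and the dye check (803, highest other 123). For gene lists in the marbled comparison 4 of 8 gave as many (5, highest other 10).

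Over all 17061 probes 463 differed between the breeds when the difference itself was tested with limma, and the named genes among them include the 4 largest in each direction by choice. Higher in Hereford were INHA (1.94 log2), LXN (1.80), EPHB3 (1.53), MB (1.43), TNNC2 (1.16), ME1 (0.98), TPI1 (0.92), HSPA8 (0.92) and GYG1 (0.74). Lower in Hereford were C4A (-2.36), RRAD (-2.16), GADD45B (-2.08), CFB (-1.84), CFD (-1.58), ZFP36 (-0.93) and CPT1B (-0.71). A dye effect adds up in these differences. The ratios of TNNC2 and TPI1 in Holstein-Friesian and of CPT1B in Hereford shrank in the same dye, as given above. Dye may therefore account for much of the difference in these genes, and same-dye differences of single genes are not given here. In the camera test of lists, 5 differed: glycolysis (0.64), fast-twitch (0.51) and heat shock (0.25) genes higher in Hereford, and immediate early (-0.997) and macrophage (-0.63) genes lower. With an estimated correlation 0 of the 5 passed (3 lists at an unadjusted p under 0.05; 3 passed in fry). In the same dye the fast-twitch difference had the opposite sign (-0.06), and glycolysis (0.27, camera adjusted p = 0.0581) and heat shock genes (0.20, 0.0815) did not pass.

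A replicate stood far from the others in 7 of 152 groups of 4 values, where chance gives about 1 in 20, or 7.6. SLC16A6 had 4.51 log2 in Hereford replicate 1, and Hereford replicate 3 had -0.70 for PLAC8B and -0.83 for RTP4. COL3A1 had -4.23 in Holstein-Friesian replicate 3. Of the bull means, GPI had -0.26 in replicate 4 and GPAM 0.74 in replicate 3. The dye check of Limousin bull 1 had an SD across probes of 0.290, against 0.199 to 0.211 in the others.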

How the results depend on the processing

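Same-dye forms for the difference, its lists and the overlap were chosen after the data were seen; the others were planned. The cause was not tested for any value below unless the construction shows it. Counts of called probes were 1218 (Hereford), 1100 (Holstein-Friesian), 102 (marbled), 463 (difference), 199 (both breeds) and 803 (dye check). Median centring gave 315, 6678, 950, 6219 and, in both breeds, 63. Processed signals gave 2411 in Holstein-Friesian, 433 marbled, 1342 for the difference and 0 in the dye check (limma; 4654 at an unadjusted p under 0.05), and the deposited ratios 2129, 438 and 979 for the first 3 of these. Array weights gave 2233, 797 and 988 for the same. The trended robust prior gave 740 in Hereford, 677 in Holstein-Friesian, 0 marbled (limma; 2805 at an unadjusted p under 0.05) and 44 in both. The same dye gave 371 in Hereford, 205 in Holstein-Friesian, 282 for the difference and 16 in both. Only its 4 arrays gave 27 in Hereford but 839 in Holstein-Friesian, and a minimum of 1.5-fold gave 560 in Hereford and 589 in Holstein-Friesian, fewer by construction. For the marbled breeds, no background subtraction gave 222, no filter 42, readings all above background 371, a random replicate block 910 and no block 1750. The replicate block, or pairing by bull, gave 701 for the difference, 1191 in Hereford and 1080 in Holstein-Friesian; of its calls 1111 in Hereford, 993 in Holstein-Friesian and 325 for the difference were shared with the counts above, and the named genes and lists it changed are in the report. An unadjusted p under 0.05 gave 1026 in both breeds, against a mean of 139 in the simulated draws with shared bulls and no breed effect.

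Leaving out 1 replicate gave 30 to 1055 in Hereford, 78 to 810 in Holstein-Friesian, 0 to 1 marbled, 0 to 457 for the difference, 5 to 123 in both and 0 to 5663 in the dye check, all with limma (2339 to 3340 marbled, 2217 to 3785 for the difference and 2291 to 7441 in the dye check at an unadjusted p under 0.05). Of the marbled lists, 5 with camera, 0 passed with an estimated correlation (1 at an unadjusted p under 0.05), 1 with fry and 3 with median centring. Of the named genes and lists, 170 of 170 kept call and direction with Aquantile, which changes nothing by construction, as does the same dye for the marbled mean. With no background subtraction 155 did so and 3 reversed, with no filter 149 and 0, with processed signals 142 and 2, with the deposited ratios 143 and 1, with median centring 119 and 13, with array weights 122 and 4, in the same dye 116 and 5, with the trended robust prior 116 and 0, and without replicates 1 to 4 in turn 118 and 2, 91 and 4, 111 and 3, and 95 and 5. Of 21 lists called in camera, 9 kept their call with fry and 0 with an estimated correlation (at an unadjusted p under 0.05, 0 lists in Hereford, 2 in Holstein-Friesian, 1 marbled and 3 for the difference).

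Reversed values of the genes and lists reported here follow, nearly all of genes that had not passed; PPARD in Hereford, RPL3, DECR1 and the ribosomal list in Holstein-Friesian and the fast-twitch list of the difference had. Median centring gave, in Holstein-Friesian, -0.45 for the ribosomal list, -0.29 for RPL3, -0.29 for RPS6, 0.026 for THRSP, -0.0069 for DECR1, -0.090 for PPARG and 0.40 for LEP; as all probes moved to -0.199 there, DECR1 (0.19) and PPARG (0.11) kept their sign relative to all probes. It gave -0.13 for LEP and 0.17 for MSTN in Hereford, and 0.13 for LEP, 0.033 for THRSP and -0.077 for LPL in the marbled breeds. The same dye gave -0.064 for the fast-twitch list of the difference, 0.090 for ZNF423, 0.14 for PPARD and -0.090 for THRSP in Hereford, and 0.070 for LPL in Holstein-Friesian. Array weights gave -0.27 for FABP4, -0.0030 for PPARG and 0.0087 for MSTN in Hereford and -0.015 for LPL in the marbled breeds. Processed signals gave 0.0067 for MSTN in Hereford (-0.080 relative to all probes, its sign kept) and 0.10 for LEP in the marbled breeds, where the deposited ratios gave 0.092. No background subtraction gave 0.018 for LEP and 0.010 for LPL in Holstein-Friesian and 0.011 for LEP in the marbled breeds. Relative to all probes, LPL in Holstein-Friesian stood at 0.014 as reported and kept that sign here, in the same dye and without replicate 4.

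Leaving out 1 replicate also turned signs, given here as lowest to highest. In Hereford, FABP4 ranged from -0.34 (without replicate 1) to 1.10, PPARG from -0.017 (without 3) to 0.24, LEP from -0.011 (without 2) to 0.051, and MSTN from -0.17 to 0.18 (without 1; 0.077 without 2). In Holstein-Friesian, FABP4 ranged from -1.21 to 0.032, LEP from -0.045 to 0.0074 and LPL from -0.25 to 0.42, each highest without replicate 4. In the marbled breeds, FABP4 ranged from -0.65 to 0.55 (without 4; 0.34 without 2), SCD from -0.34 to 0.0042 (without 2), LEP ranged from -0.020 to 0.012 (without 4; 0.0059 without 3), and LPL from -0.057 (without 3) to 0.29. Signal over background limited the Holstein-Friesian readings most, with 13939 to 14823 of 21475 probes well above background, so ratios of dim genes such as LEP are pulled towards 0. These readings were all in Cy3 on 1 slide, so the low signal need not be a trait of the breed.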

Other observations

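The test of fat cells in the sample was written before its result was seen.

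MT2A stood lower than in Limousin on all 8 arrays, in both dyes and on both slides, and with GADD45G, KLF4, ZFP36 and JUN it kept its Holstein-Friesian call without each replicate in turn, and with CPT1B its Hereford call. Its same-dye ratios were -3.27 in Hereford and -3.26 in Holstein-Friesian, and the Limousin dye check gave -0.18. Metallothionein genes respond to zinc and to glucocorticoids, neither of which was measured here.

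FABP4 varied widely between bulls of a breed, so the hypothesis was tested that the number of fat cells caught in a sample sets its level. Each bull's FABP4 deviation from its breed mean was set against the mean deviation of 14 other measured genes of the adipocyte list. Over 12 bulls Pearson's r was 0.802 (permutation p = 0.00311, 1e+05 resamples within breeds) and Spearman's rho 0.727 (permutation p = 0.0103), as 1 relation tested. Without the 2 bulls farthest from the median r was 0.599, and within breeds it was 0.888 for Hereford, 0.797 for Holstein-Friesian and 0.738 for Limousin, with only 4 bulls each. Of the 14 genes, 12 had an r above 0 with FABP4 and 5 an r above 0.5, namely CIDEC (0.853), THRSP (0.731), PLIN1 (0.678), RBP4 (0.574) and G0S2 (0.540). The mean was not scaled by gene, so CIDEC, which varied most (SD 0.820), weighs most in it. THRSP varied little (SD 0.0656), at a low mean log2 intensity of 6.59.

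These values are consistent with a varying amount of fat tissue in the samples, with r at 0.802. The highest FABP4 deviations were 2.01 in Hereford replicate 1 and 1.61 in Limousin bull 4, and the lowest -1.75 in Hereford replicate 2 and -1.22 in Limousin bull 3. FABP4 varied with an SD of 1.06 log2 over the bulls and CIDEC with 0.820, at mean log2 intensities of 8.60 and 7.80. The most intense list members, CEBPA (14.8) and AGPAT2 (13.1), had an r of 0.163 and 0.0857 with FABP4. None of the 20 list genes is in another list (0 shared), but muscle fibres express some of them, a number not measured here. No sort of cells is given in the sources used here.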
